A study of Zea mays with 94 samples.

How the data were processed

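Illumina RNA sequencing of leaf, ear and tassel from B73 maize at stages V12, V14, V16 and R1, under well-watered and drought conditions, gave 94 libraries in 24 groups of 3 or 4. The labels gave the tissue, stage, water treatment and replicate number of every library. The reads were processed with CASAVA, TopHat2, Cufflinks and Cuffdiff, per the submitters' processing notes, which give no version, role or order. The deposited table holds each transcript's abundance in percent of its gene in each library, as the authors computed it, although its name speaks of FPKM. This was tested on the values: in 93.56% of the pairs of gene and library with a value the transcripts of a gene sum to 100 within 0.1, and in 0.9712% to under 0.1. A missing value always covers all transcripts of a gene, and what it stands for is not stated. Each transcript also carries its class (known to the reference annotation or not), closest reference transcript, locus, cDNA sequence with its length and predicted protein length, all as deposited. The genome build is not given in the sources used here.

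The comparisons were laid out before the data were examined on the assumption that the table held FPKM. Because it holds percentages, the tests of gene level and their alternatives were not run, and usage was taken as deposited, with no pseudocount and no filter on FPKM. Depth per library is unknown, so no precision from counting can be given. Transcripts were assigned to the gene of their closest reference transcript. Reference genes were matched to the RefSeq annotation of the assembly Zm-B73-REFERENCE-NAM-5.0 by locus tag: 18782 of 109771 matched and 2644 of these have a name other than a clone or locus number. No genome was used.

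Usage was compared with limma 3.58.1 in R 4.3.3 (lmFit, contrasts.fit and eBayes with trend; data.table version 1.17.8 for reading the file). Each fit held 1 mean per group, over all libraries of an organ for drought, development and stage interactions, and over all 94 libraries for organs and their interaction. Tested were genes with at least 2 transcripts and a value in every library of the fit, and of these the transcripts with a mean usage from 5% to 95%. A gene was called if a transcript had a Benjamini-Hochberg adjusted p below 0.05 and a change of at least 10 points. Interactions used the F test of limma, with at least 10 points between the largest and smallest effect. The effective number of isoforms was the exponential of the Shannon entropy of usage, averaged over the tested genes of an organ, and compared by permuting water labels within stages (1e+05 resamples, seed 20, two-sided). Single values per library were compared by two-sided exact permutation tests, adjusted over the comparisons of each measure. The smallest p of 4 against 4 and of 4 against 3 libraries is 0.0286. Genes with a value in more libraries of an organ than of another were found by Fisher's exact test per gene, two-sided and adjusted over all genes with a value, a comparison added after the unit of the table was known.

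Transcripts of a gene were compared by their cDNA with a script in Python 3.11.15 (numpy 2.4.6; figures with matplotlib 3.10.9), which joins shared words of 20 nt into blocks. An extra internal segment of at least 50 nt that starts with GT and ends with AG counted as a retained intron, and an end difference needed at least 50 nt. Of 1200 simulated pairs 1195 were classed as made. Over the 2 most used transcripts of 14086 genes with a value in all libraries, 2584 pairs (18.3%) were retained introns, 3630 (25.8%) other internal segments and 5738 (40.7%) other end differences. A library's share for a class is the mean over its pairs of the usage of the longer or retaining transcript in percent of the pair. The share of the longer 5′ end rests on the 148 pairs (1.05%) where 1 transcript starts inside the other. That of the longer 3′ end rests on the 268 pairs (1.9%) where 1 stops inside the other. Other end differences enter neither. An exchanged pair was the most gained and the most lost transcript of a called gene.

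The usage test was tested on simulated data made from the real means and residuals with no group effect, in which usage was moved between transcripts in 50 genes per shift. At shifts of 10, 15, 20 and 40 points it recovered 4, 10, 25 and 41 in leaf drought, 0, 2, 9 and 26 in leaf drought at R1, 0, 1, 8 and 30 in tassel development, and 9, 16, 24 and 47 between tassel and leaf. In these runs 0 unshifted genes were called by limma. Residuals were shuffled only within their own group, where they average 0, so the group means of an unshifted gene were alike by construction. The count of unshifted genes therefore gives no rate of false calls.

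Genes with a symbol were followed by name by a rule fixed before the data were examined. Per contrast these were the 5 called genes with the largest change, for interactions the 3 with the smallest adjusted p, and for each list and contrast up to 4 called members with the largest change. Only part of them is printed. Between organs, the genes printed with values were, but for dek1, among those that kept their call in every alternative fit, so they are not typical of the genes followed. The 28 lists, also fixed before the data were examined, cover light harvesting proteins, photosystem subunits, C4 cycle enzymes, Calvin cycle enzymes, dehydrins and other LEA proteins, heat shock proteins and factors, abscisic acid genes, osmoprotectant synthesis, sucrose genes, aquaporins, oxidative stress enzymes, core histones, cell cycle genes, cytosolic ribosomal proteins, splicing factors, MADS-box genes, meristem regulators, pollen and anther genes, cell wall genes, wax and lipid transfer, senescence, defence, auxin response, ethylene, kernel storage, clock and flowering, lignin and anthocyanin genes. Members were matched by symbol or synonym, so lists can hold genes that share a symbol with a member: the C4 list holds PDK1, whose synonym pdlk1 names a pyruvate dehydrogenase kinase, and the MADS-box list holds M2, which has the synonym myosin. Lists with at least 5 tested members were compared with all tested genes that have a symbol by Fisher's exact test, since usage has no common direction for a directional set test.

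Alternatives were a change of at least 20 points, the replicate number as a block, reference transcripts only with usage recomputed, limma's diffSplice on log2 of the percent plus 0.5, and leaving out each library. Added after the data were seen were the usage-weighted mean transcript length of each library as a covariate, leaving out 6 libraries of short mean length, fits on the compared groups alone, and the drought libraries in place of well-watered ones. Named genes were followed through those alternatives that refit the same transcript, not through the 20-point threshold or diffSplice. Label splits were enumerated (35 for 4 against 4 or 4 against 3) or drawn (100, the real one included), within stages where stages were pooled. For the interactions no labels were split. There the residuals of a fit without the tested interaction were shuffled over all libraries of the fit (100 counts, the real one included).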

Results

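RNA sequencing measured transcript isoforms in leaves, ears and tassels of field-grown B73, the maize inbred line from which the reference genome of the species was built. Libraries came from the vegetative stages V12, V14 and V16, which are named by leaf number, and from R1, when silks emerge. Plants were well watered or left without water after stage V8. The 24 groups of tissue, stage and water held 4 libraries each, except well-watered tassel at R1 and drought tassel at V12, which held 3, for a total of 94. According to the labels the plots followed a randomized complete block design with 4 biological replicates, so the p-values reach no further than a single experiment. Tests pooled over stages or organs took all their libraries as independent. If libraries of different stages or organs came from the same plots, those p-values can be too small. Each value was an isoform usage, the percentage of the transcript abundance of a gene that a transcript took. The file held rows for 187969 transcripts of 109771 reference genes, of which 25188 had at least 2 transcripts, and 48432 of the transcripts lay outside the reference annotation. Of all 187969 transcripts, 42500 had no value in any library, and 68480 genes had a value in at least 1. Read depth is unknown, because the deposited values are percentages, and the genome build of the coordinates is not given in the sources used here. From 29520 to 38450 genes had a value per library, and no 2 libraries held identical values (correlations between 0.1804 and 0.9029). Usage differences are in percentage points. A gene was called when a transcript passed a Benjamini-Hochberg adjusted p of 0.05 in limma and differed by at least 10 points. Where stages were pooled each stage weighed the same in that difference, while printed means are over libraries, so their difference can depart from it where a group held 3.

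Which isoforms separate the 3 organs was examined first, in well-watered plants and over all 4 stages. In mbd106 (GRMZM2G022365, chromosome 1, 175294550 to 175302644), which encodes a methyl-CpG-binding domain protein, a reference transcript took 98.6% ± 2.55 of the gene in ear (SD, n = 16) against 0.189% ± 0.755 in leaf (n = 16; adjusted p = 1.67e-50, limma). Its partner lacked a 49-nt internal segment. In the beta-tubulin gene TUBB2 (GRMZM2G334899, chromosome 8, 104770563 to 104774039) the transcript that took 96.9% ± 12.4 in leaf was at 0.489% ± 1.92 in ear (adjusted p = 4.9e-24, limma). A form retaining a 75-nt intron replaced it. Usage of a kin11 transcript (GRMZM2G436981) was 0.869% ± 2.31 in ear and 96.8% ± 11.3 in leaf, and that of a MAGE transcript (GRMZM2G142119) was 1.25% ± 1.71 and 93% ± 9.55. In these 2 genes 16 and 16 of the 16 ear libraries lay on the same side of the leaf mean. For cyclin4 (GRMZM2G310115), a cell cycle cyclin, the main leaf transcript was at 97.7% ± 1.74 in leaf and 12.6% ± 5.33 in ear. The cyclin4 transcripts exchanged share no sequence block and are joined only by their reference gene name.

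Among the gene groups fixed in advance, 4 of 10 tested MADS-box genes differed between ear and leaf (4 adjusted over the list alone). They included mad2 (GRMZM2G047143), whose main ear transcript was at 78.3% ± 2.7 in ear and 19.9% ± 22.9 in leaf, and MADS76 (GRMZM2G070034), with 15.1% ± 7.8 and 1.14% ± 0.721. Of the abscisic acid genes 4 of 10 were called (4 adjusted over the list alone), among them ABI14 (GRMZM2G106673) with 32.3% ± 13.1 in ear and 9.85% ± 6.5 in leaf. Of 12 oxidative stress enzymes 4 were called (4 adjusted over the list alone). A transcript of the glutathione transferase gst37 (GRMZM2G178079) was at 48.5% ± 22.6 in leaf and 3.41% ± 13.6 in ear. Clock and flowering genes were called in 4 of 5 cases (4 adjusted over the list alone), with a ZCN18 transcript (GRMZM2G158809) at 7.85% ± 11 in ear and 70.8% ± 6.82 in leaf. Of 14 cytosolic ribosomal proteins 2 were called (2 adjusted over the list alone). Of 5 genes of the C4 list 0 were called in limma (0 adjusted over the list alone, 2 at an unadjusted p below 0.05). Over all 12851 genes tested, 4981 (38.8%) differed, 478 of them among 1236 genes with a name. In the 4950 called genes with a pair of exchanged transcripts, 848 pairs differed by a retained intron. The retaining transcript was the one gained in ear in 549 and lost in 299. Other longer forms moved alike. Another 1210 pairs differed by another internal segment, and the form with it was gained in 838 and lost in 372. The transcript gained in ear coded a longer protein in 2863 pairs and a shorter one in 1285. With transcripts of the reference annotation alone 1837 genes were called. Of the 54 genes followed by name 16 kept their call in every alternative fit of the same transcript.

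Tassel and leaf shared some of these contrasts. The mbd106 transcript took 99.4% ± 1.17 in tassel (n = 15) and the leaf form of TUBB2 0.21% ± 0.792, with adjusted p of 5.87e-50 and 1.3e-23 against leaf (limma). A transcript of Amy2 (GRMZM2G058310), which encodes an amylase, was at 79.9% ± 29.1 in tassel and 1.39% ± 0.771 in leaf. In ERECTA (GRMZM5G809695, chromosome 6, 108197029 to 108204687), a receptor kinase gene of organ growth, a transcript outside the reference annotation was at 77.3% ± 13.5 in leaf and 3.29% ± 4 in tassel. The form gained coded for 994 instead of 437 amino acids. The heat tolerance chaperone hsp101 (GRMZM2G360681) used its shorter-coding form at 31% ± 5.34 in tassel and 5.07% ± 6.4 in leaf. For gigz1b (GRMZM5G844173), a GIGANTEA gene of the circadian clock, a form of 792 amino acids was at 73.5% ± 8.89 in leaf and 12.6% ± 8.29 in tassel.

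Clock and flowering genes were called between tassel and leaf in 5 of 5 cases. The count adjusted over the list alone, given in brackets from here on, was the same (5). The other large shares were 10 of 13 auxin response genes (10), 5 of 6 splicing factors (5), and 4 of 5 each for the C4 list, core histones and cell wall genes (4 each). The splicing factor SRP2B (GRMZM2G021223) had its main leaf transcript at 44.3% ± 6.67 in tassel and 61% ± 16.8 in leaf. C4ppdkZm1 (GRMZM2G306345), the pyruvate orthophosphate dikinase of C4 photosynthesis, had a short-coding transcript at 53.2% ± 14.9 and 75.6% ± 3.55. Called were also 6 of 10 heat shock genes (6), 6 of 10 abscisic acid genes (6), 3 of 7 aquaporins (3) and 3 of 12 oxidative stress enzymes (3). The remaining tested lists gave 3 of 10 MADS-box genes (3), 3 of 5 pollen and anther genes (3), 5 of 8 defence genes (5) and 3 of 6 ethylene genes (3). Cytosolic ribosomal proteins were called in 3 of 14 cases (2), against 801 of 1236 for all genes with a name. This was the smallest p of all list tests (two-sided Fisher's exact test, p = 0.0011, adjusted p = 0.132), so no list passed correction in any comparison. In the ribosomal protein gene rpl35A (GRMZM2G177098) a transcript was at 92.6% ± 12.4 in tassel and 23.2% ± 5.46 in leaf, and its partner shares no sequence block with it.

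Lists with fewer than 5 tested members were not tested as lists. Between tassel and leaf they gave 1 of 4 light harvesting proteins (1 adjusted over the list alone), 1 of 1 photosystem subunits (1), 1 of 1 dehydrins and other LEA proteins (1) and 1 of 4 sucrose genes (0). Further counts were 3 of 4 cell cycle genes (3), 2 of 4 meristem regulators (2), 1 of 3 genes of wax and lipid transfer (1), 1 of 2 senescence genes (1), 1 of 2 lignin enzymes (1) and 1 of 1 anthocyanin genes (1). Of the Calvin cycle enzymes 0 of 1 were called in limma (0, and 0 at an unadjusted p below 0.05). The light harvesting member was CP24 (GRMZM2G092427), an antenna protein of photosystem II, with 36.9% ± 7.86 in tassel and 70.9% ± 17.4 in leaf for the transcript coding 248 amino acids. Under drought, 0 of 1 osmoprotectant genes were called in leaf (0 adjusted over the list alone, 1 at an unadjusted p below 0.05 in limma). In drought tassel 0 of 1 kernel storage genes were (0, and 0 at an unadjusted p below 0.05).

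Between tassel and ear, dek1 (GRMZM2G321753, chromosome 1, 47290561 to 47326697) encodes a calpain-type protease that the outer cell layer of the kernel needs. Its transcript coding 282 amino acids was at 22.7% ± 20.2 in tassel and 73.5% ± 17 in ear (adjusted p = 4.52e-27, limma), and the transcript gained coded 1503. The dek1 call ended when transcripts outside the reference annotation were left out. A transcript of hxa103 (GRMZM2G129817) was at 11.3% ± 18.1 in tassel and 58.6% ± 19.2 in ear, and one of the cellulose synthase gene cesa10 (GRMZM2G445905) at 44.7% ± 35.5 and 92.2% ± 10.4. The longer-coding CP24 transcript was at 82% ± 22.6 in ear and 36.9% ± 7.86 in tassel. The long form of CER1 (GRMZM2G066578), a gene of wax synthesis, was at 41.7% ± 14.4 in tassel and 17.1% ± 21.2 in ear. Clock and flowering genes were again called in 5 of 5 cases (5 adjusted over the list alone) and auxin response genes in 9 of 13 (9). Calls were fewer for splicing factors, 1 of 6 (1), and cytosolic ribosomal proteins, 1 of 14 (1). Of 6 ethylene genes 0 were called in limma (0 adjusted over the list alone, 1 at an unadjusted p below 0.05).

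Tassel differed from leaf in 8413 of the 12851 genes (65.5%) and from ear in 6256 (48.7%). Mean transcript length, weighted by usage, was 1783 ± 6.58 nt in tassel (SD, n = 15), 1684 ± 21.9 nt in leaf (n = 16) and 1715 ± 59.0 nt in ear (n = 16). Where transcripts of a gene differ at the 5′ end, the longer one took 31.7% ± 1.37, 20.7% ± 2.64 and 23.6% ± 5.84 in the 3 organs. With the mean transcript length of each library as a covariate the counts were 4155 for tassel and leaf and 3072 for tassel and ear. With reference transcripts alone they were 2901 and 2005. Of the genes followed by name, 21 of 72 (tassel and leaf) and 15 of 49 (tassel and ear) kept their call in every alternative fit of the same transcript. With the covariate 14 of the 72 and 8 of the 49 reversed. Tassel libraries also carry library numbers of a separate series in the labels, so organ and library series cannot be told apart in comparisons with tassel.

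How isoforms change as each organ develops was tested from V12 to R1 in well-watered plants, where the tassel gave the most calls. In the drought libraries the order differed, with 8348 calls in ear, 2028 in tassel and 843 in leaf. Among called genes with a symbol, the largest change in well-watered tassel was in serk1 (GRMZM5G870959, chromosome 10, 121751970 to 121757411), a somatic embryogenesis receptor kinase gene. There a transcript fell from 99.9% ± 0.0801 at V12 (SD, n = 4) to 0.654% ± 0.553 at R1 (n = 3; adjusted p = 1.72e-05, limma), but differed by 3.13 points in the opposite direction between the drought libraries of these stages. In DET2 (GRMZM2G449033, chromosome 3, 178991214 to 178993461), the steroid reductase gene of brassinosteroid synthesis, a transcript that lacks a 72-nt internal segment rose from 2.35% ± 0.368 to 89.7% ± 8.99. CYPPDKZM2 (GRMZM2G097457), a pyruvate orthophosphate dikinase gene, gained a transcript outside the reference annotation that went from 1.1% ± 1.28 to 84% ± 3.3. The form it replaced holds a 78-nt intron. A transcript of licc1 (GRMZM2G098797) fell from 95.1% ± 4.47 to 13.5% ± 1.52, and one of PHD16 (GRMZM2G168249), a PHD finger gene, from 80.9% ± 3.08 to 0. In each of these 5 genes all 3 R1 libraries lay on the same side of the V12 mean.

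**Figure D1:**
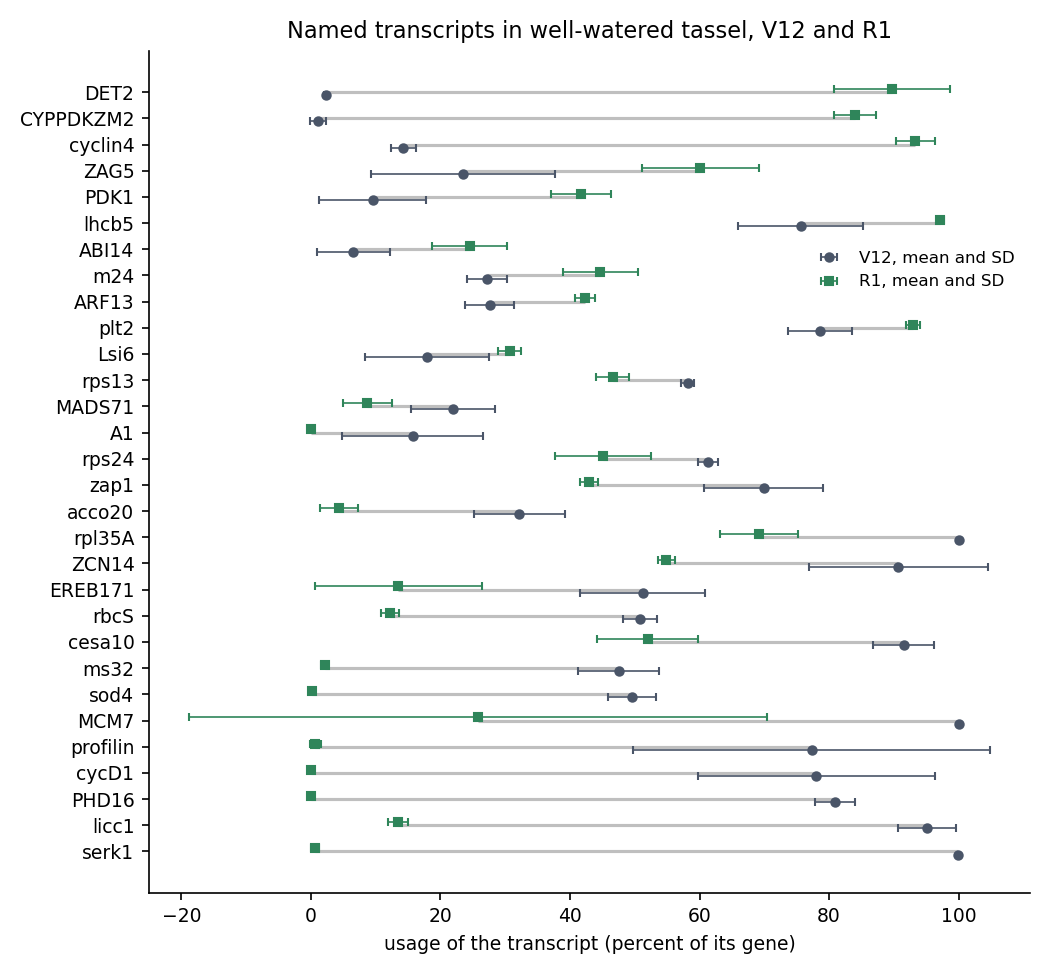
Isoform usage in percent of the gene (horizontal axis) for the 30 named transcripts called between V12 (n = 4) and R1 (n = 3) in well-watered tassel, with the mean and SD of each group joined by a line. The serk1 transcript went from 99.9% ± 0.0801 at V12 to 0.654% ± 0.553 at R1, and the DET2 transcript from 2.35% ± 0.368 to 89.7% ± 8.99.

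Cell cycle genes changed in tassel in 3 of 8 cases (4 adjusted over the list alone). The main cyclin4 transcript rose from 14.3% ± 1.96 to 93.3% ± 3.04, and that of the D-type cyclin cycD1 (GRMZM2G006721) fell from 78% ± 18.3 to 0.0213% ± 0.0158. The replication licensing gene MCM7 (GRMZM2G065205) had a transcript at 100% ± 0.0121 at V12 and 25.8% ± 44.6 at R1. The calls of cycD1 and MCM7 ended with mean transcript length as a covariate. Pollen and anther genes were called in 2 of 9 cases (2 adjusted over the list alone). One was the actin-binding profilin gene (GRMZM5G876285), with a fall from 77.3% ± 27.5 to 0.691% ± 0.813. The other was male sterile ms32 (GRMZM2G163233), with a fall from 47.5% ± 6.31 to 2.15% ± 0.546 in a transcript that shares no sequence block with its partner. Of 13 cytosolic ribosomal proteins 3 were called (3 adjusted over the list alone), of 28 MADS-box genes 4 (5) and of 11 aquaporins 1 (3). In limma 0 of 12 heat shock genes, 0 of 6 splicing factors and 0 of 10 meristem regulators were called (0 adjusted over each list alone, and 2, 3 and 1 at an unadjusted p below 0.05). The antioxidant gene sod4 (GRMZM2G169890) lost a transcript, from 49.6% ± 3.73 to 0.181% ± 0.313. The RuBisCO small subunit gene rbcS (GRMZM2G098520) lost a form that retains a 164-nt intron, from 50.8% ± 2.65 to 12.2% ± 1.42.

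Intron-retaining transcripts lost ground over tassel development. Among genes whose leading transcripts differ by a retained intron, the retaining form took 46.62% ± 0.526 at V12 (SD, n = 4), 45.98% at V14, 44.26% at V16 and 43.16% ± 0.349 at R1 (n = 3) in well-watered tassel. The difference from V12 to R1 was -3.468 points (two-sided exact permutation test, p = 0.0286, the smallest p that 4 against 3 libraries can give; adjusted p = 0.0343). In drought tassel it fell by 3.082 points (exact p = 0.0286, adjusted p = 0.0343). The ear fell by 1.929 points in well-watered plants, from 46.11% ± 0.144 to 44.18% ± 1.10 (n = 4 each; exact p = 0.0286, adjusted p = 0.0343), and the leaf differed by 0.123 points (exact p = 0.914). In drought plants the ear fell by 6.078 points and the leaf rose by 2.366 (each exact p = 0.0286, adjusted p = 0.0343). Of the 4 drought ear libraries at R1, 3 had short mean transcript lengths (1621, 1599 and 1576 nt) and shares of 39.24%, 38.27% and 36.81%, against 43.03% in library 1 and 45.42% on average at V12. In drought plants mean transcript length fell by 123.7 nt in ear and rose by 47.91 nt in leaf (each exact p = 0.0286, adjusted p = 0.0343). In well-watered plants it fell from 1787 ± 2.29 to 1775 ± 1.86 nt in tassel and from 1770 ± 6.66 to 1720 ± 21.7 nt in ear (each exact p = 0.0286, adjusted p = 0.0343). In tassel 2414 more genes had a value at R1 (exact p = 0.0286, adjusted p = 0.0429). The share of transcripts with another extra internal segment was also lower at R1 in tassel (-1.68 points in well-watered plants, exact p = 0.0286, adjusted p = 0.0571; -1.252 in drought plants, exact p = 0.0571, adjusted p = 0.0686). Of the 2293 genes with an exchanged pair in tassel, 466 pairs differed by a retained intron, and the retaining transcript was lost in 348 and gained in 118. Another 423 pairs differed by such a segment, and the form with it was lost in 251 and gained in 172. In all, 2329 of 15387 genes were called in tassel, 233 of them among 1434 with a name. The count was 961 with reference transcripts alone, 965 with the compared groups alone in the fit, and 920 with mean transcript length as a covariate. Of the 30 genes followed by name 11 kept their call in every alternative fit of the same transcript: DET2, CYPPDKZM2, licc1, PHD16, rbcS, sod4, cyclin4, rpl35A, profilin, ms32 and acco20. Transcripts at exactly 0 in every V12 and V14 library and at 5% or more in every V16 and R1 library, or the reverse, numbered 32 in well-watered and 24 in drought tassel.

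**Figure D2:**
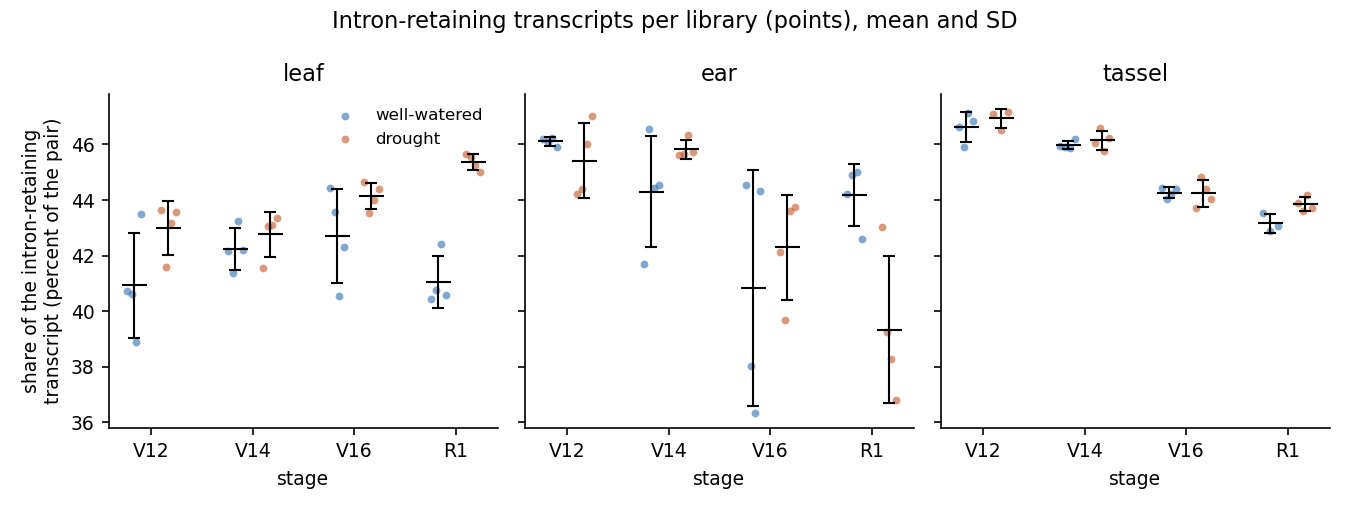
Share of the intron-retaining transcript in percent (vertical axis) by stage in each organ, with points for single libraries and bars for group means and SD. Well-watered tassel went from 46.62% at V12 to 43.16% at R1, and well-watered ear from 46.11% to 44.18%.

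Ear development called fewer genes. The MADS-box gene M14 (GRMZM2G102161, chromosome 9, 146679028 to 146698719) gained a transcript that was listed at 0 in all 4 V12 libraries and took 78.6% ± 3.17 at R1 (SD, n = 4; adjusted p = 0.000417, limma). A MYB121 transcript (GRMZM2G147346) fell from 78.7% ± 4.98 to 14% ± 18.9. These 2 of the 9 ear genes followed by name kept their call in every alternative fit. The main Amy2 transcript rose from 30.9% ± 13.4 to 96% ± 0.875, and the long CER1 transcript from 0 to 42.8% ± 13.3, and neither was called between the drought libraries. The GRF14 transcript (GRMZM2G098594) was at 3.54% ± 4.22 at V12 and 56.5% ± 30 at R1, but differed by -0.0247 points in the drought libraries. Of 17 MADS-box genes 2 were called in ear (4 adjusted over the list alone), M14 and m22 (GRMZM2G171650; 18.1% ± 4.9 to 1.41% ± 1.04). Of 12 cell cycle genes 0 were called in limma (4 adjusted over the list alone, 6 at an unadjusted p below 0.05). The single call among 10 heat shock genes (1 adjusted over the list alone) was hsp101, with its shorter-coding form at 27.1% ± 4.69 at V12 and 8.62% ± 4.79 at R1. The calls of m22 and hsp101 ended when some single libraries were left out. The ear count was 224 of 14736 genes, 22 of them named. Leaving out V12 library 1 gave 134, and leaving out R1 libraries 1, 2, 3 or 4 gave 133, 120, 115 and 127. The count was 102 with reference transcripts alone, but 594 with the compared groups alone in the fit and 453 by diffSplice. In the drought libraries the same comparison called 8348 genes, with 3 of the 4 R1 libraries at mean transcript lengths of 1576, 1599 and 1621 nt.

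In leaf, AGA3b (GRMZM2G037265) rose from 0.0194% ± 0.0388 at V12 to 97.8% ± 2.56 at R1 (SD, n = 4 each; adjusted p = 0.00345, limma). Coilin (GRMZM2G136624), which encodes the scaffold of Cajal bodies, fell from 72.9% ± 31.2 to 2.55% ± 5.11. A PMP3 transcript (GRMZM2G477325) was at 89.1% ± 12.7 and 34.1% ± 27.8, and one of the metal transporter gene Nramp1 (GRMZM2G147560) at 100% ± 0.0405 and 55.1% ± 22.6. These were the 4 named genes among 73 called of 14626 in leaf. Of the 4, 0 kept their call in every alternative fit, and between the drought libraries AGA3b, Coilin and PMP3 were not called and Nramp1 differed by 1.12 points. The 73 calls (2887 genes at an unadjusted p below 0.05 in limma, 479 by diffSplice) became 45 to 178 with single libraries left out, 40 with reference transcripts alone and 7 with the compared groups alone in the fit. Of 35 splits of the labels 3, the real one included, called 73 genes or more, with a highest count of 92. Of 5 cell wall genes 0 were called over all genes in limma (1 adjusted over the list alone, 1 at an unadjusted p below 0.05). The same counts were 0 of 11 for abscisic acid genes (0 and 4) and 0 of 14 for auxin response genes (0 and 3).

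Withheld water gave the fewest calls in tassel. A transcript of glct1 (GRMZM2G153704, chromosome 8, 12786792 to 12801402) was at 40.2% ± 9.52 in drought (SD, n = 15) and 24.2% ± 22.7 in well-watered tassel (adjusted p = 0.015, limma). It was 1 of 7 genes followed by name to keep its call in every alternative fit. The starch phosphorylase gene pho1 (GRMZM2G074158) had 25.8% ± 7.08 and 11.3% ± 9.79 for a transcript outside the reference annotation, and gol1 (GRMZM2G080079) had 19.7% ± 12.2 and 34.1% ± 8.88. Values were 54.6% ± 6.89 and 69.8% ± 13.1 for CK2 (GRMZM2G047855), and 47.7% ± 15.7 and 36.4% ± 13.5 for SC30 (GRMZM2G016296). The calls of pho1, CK2 and SC30 ended when some single libraries were left out, and that of gol1 with reference transcripts alone. Of 8 ethylene genes 1 was called (1 adjusted over the list alone), the ACC oxidase acco20 (GRMZM2G126732; 68.8% ± 17.5 in drought, 77.6% ± 12.5 watered, -11 points with equal stages), whose call also ended when some libraries were left out. In limma 0 of 12 heat shock genes, 0 of 11 abscisic acid genes, 0 of 11 aquaporins, 0 of 13 oxidative stress enzymes and 0 of 6 splicing factors were called. Each had 0 adjusted over the list alone, and 4, 2, 2, 4 and 2 had an unadjusted p below 0.05. Over the 4 stages 103 of 15387 genes were called, 12 of them named (3371 genes at an unadjusted p below 0.05 in limma, 290 by diffSplice). At V12, V14, V16 and R1 the counts were 158, 103, 8 and 92, and with the compared stage alone in the fit 1, 13, 1 and 5. Leaving out single libraries gave 68 to 131 over the 4 stages, 51 to 104 at V14, 2 to 17 at V16 and 70 to 192 at R1. Reference transcripts alone gave 26 over the 4 stages. Other splits of the labels called up to 127 genes at V12 and 60 at R1. At V16, 3 of 35 splits of the labels, the real one included, called 8 genes or more.

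Leaf gave 3644 calls of 14626 genes under drought and ear 1847 of 14736. Among called genes with a symbol, the leading ones were nearly the same in both. The main transcript of nfc103 (GRMZM2G023372, chromosome 1, 251956590 to 251967052) fell from 100% ± 0.00111 in well-watered to 6.41% ± 14.2 in drought leaf (SD, n = 16; adjusted p = 3.82e-17, limma) and from 98.6% ± 5.44 to 0.0562% ± 0.206 in ear. The brachytic2 gene of polar auxin transport, br2 (GRMZM2G315375, chromosome 1, 202226326 to 202313358), had its main transcript fall from 99.3% ± 1.52 to 8.91% ± 2.96 in leaf and from 99.2% ± 1.09 to 16.3% ± 10.3 in ear. A rcalm transcript (GRMZM2G004703) fell from 82.7% ± 8.72 to 0 in leaf and from 82.3% ± 2.7 to 0 in ear. An elfa7 transcript (GRMZM2G110509), of the elongation factor 1-alpha family, rose from 0 to 72.1% ± 8.36 in leaf and was at 0 and 73.2% ± 8.37 in ear. LIM6 (GRMZM2G128206) fell from 98.7% ± 0.707 to 27.5% ± 8.18 in leaf and from 99% ± 0.468 to 17.2% ± 12.2 in ear. In drought tassel the same 5 transcripts were at 98.2% ± 6.92, 98.1% ± 1.75, 69.1% ± 8.92, 0 and 98.9% ± 1.01 (n = 15). In well-watered tassel they were at 100% ± 0.000972, 97.9% ± 1.79, 68.3% ± 8.76, 0 and 98.7% ± 0.507 (n = 15).

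**Figure D3:**
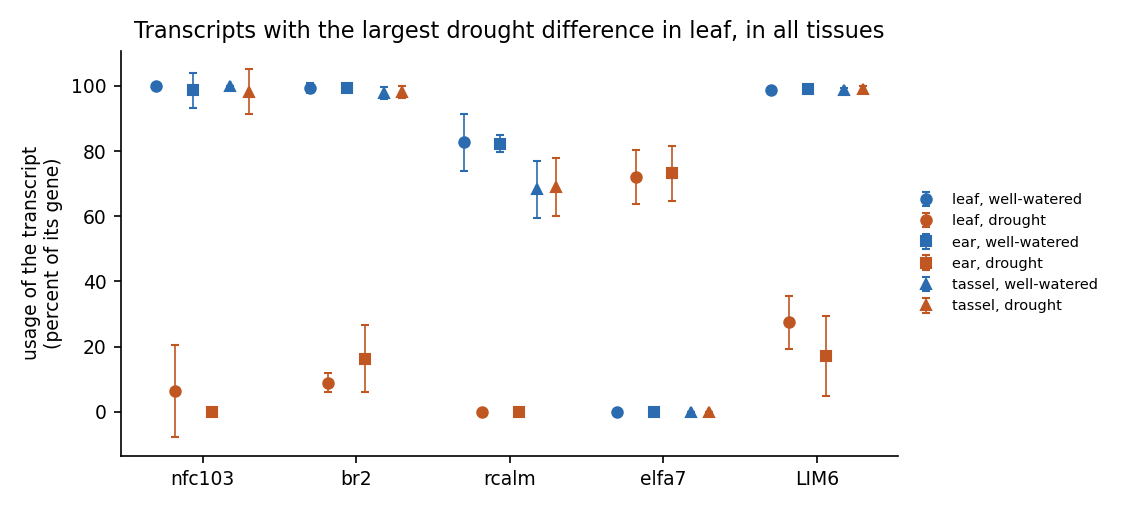
Isoform usage in percent of the gene (vertical axis) of the 5 transcripts with the largest drought difference in leaf among called genes with a symbol, as mean and SD in well-watered and drought libraries of leaf (n = 16 each), ear (n = 16 each) and tassel (n = 15 each). The br2 transcript was at 99.3% and 8.91% in leaf, 99.2% and 16.3% in ear, and 97.9% and 98.1% in tassel.

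These drought calls in leaf and ear moved with a difference between whole sets of libraries. Drought leaf libraries had a value for 36790 ± 491.8 genes at V12 against 30800 ± 1074 in well-watered ones (SD, n = 4 each), a difference of 5998. The differences were 6349 at V14, 5716 at V16 and 7919 at R1 in leaf, and 6174, 6038 and 5868 at V12, V14 and V16 in ear (two-sided exact permutation tests, each p = 0.0286, adjusted p = 0.049). At R1 the ear difference was 2647 (exact p = 0.143), and in tassel the differences were 341.2, -52.25, 533.8 and 722.3 (the smallest exact p was 0.171). Transcripts at exactly 0 in every library of one water treatment and at 5% or more in every library of the other numbered 82 in leaf, 50 in ear and 0 in tassel. Of 64 such transcripts gained in drought leaf that had a value in all ear libraries, 25 met the same rule in ear. On average over libraries 62 were under 1% in well-watered and at 5% or more in drought ear. Genes called in both leaf and ear numbered 972, against 431 for independent lists, with the same direction in 829 of the 955 that could be compared. Leaf and tassel shared 17 (23.5 for independent lists) and ear and tassel 22 (11.5). Over all 5169 transcripts called in leaf and tested in ear, 52.2% moved in the leaf direction in ear, with a median of 0.816 points. With mean transcript length as a covariate, 651 of 977 leaf calls tested in ear were also called there (125 for independent lists). The direction was the same in 634 of the 639 that could be compared. In that fit leaf and tassel shared 7 (7.61) and ear and tassel 19 (13.4).

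**Figure D4:**
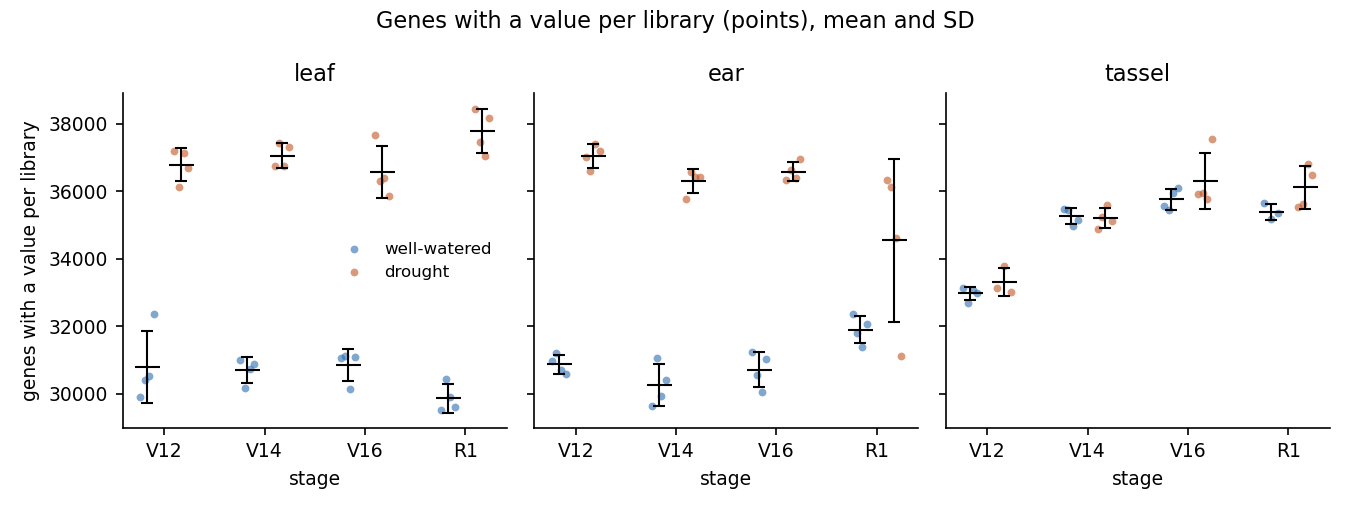
Number of genes with a value (vertical axis) in each of the 94 libraries, by organ, stage and water, with bars for group means and SD. Drought libraries of leaf averaged 36560 to 37790 genes by stage and well-watered ones 29870 to 30850, while the largest difference between water treatments within a stage of tassel was 722.3.

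With that set difference beside them, the drought calls in leaf included 5 of 18 oxidative stress enzymes (5 adjusted over the list alone), 4 of 12 heat shock genes (4), 3 of 11 abscisic acid genes (3) and 3 of 15 cytosolic ribosomal proteins (3). The counts were 2 of 6 each for the C4 list, sucrose genes, and clock and flowering genes (2 each). They were 2 of 9 for aquaporins (2) and 2 of 14 for auxin response genes (2). Of 6 splicing factors 0 were called in limma (0, with 2 at an unadjusted p below 0.05). PDK1 (GRMZM2G107196), which the C4 list took in by its symbol although its synonym pdlk1 names a pyruvate dehydrogenase kinase, had a transcript at 63.6% ± 12.1 in drought and 4.28% ± 7.63 in well-watered leaf. The sucrose synthase sus2 (GRMZM2G318780) had 29.7% ± 14.8 and 63.6% ± 11.1. For the silicon transporter Lsi6 (GRMZM2G081239) the values were 79.7% ± 10.6 and 42.1% ± 19.4, and the form that retains a 563-nt intron was the one lost. The glutathione transferases gst20 (GRMZM2G056388) and gst37 had 49.3% ± 23.4 against 3.98% ± 9.41 and 3.84% ± 4.28 against 34.2% ± 19.9, and ribosomal rps6 (GRMZM2G054136) had 34% ± 1.77 against 0.0232% ± 0.00301. These 6 were among the 14 of 39 leaf genes followed by name that kept their call in every alternative fit. Stage counts in leaf were 659 at V12, 591 at V14, 1046 at V16 and 4598 at R1. With mean transcript length as a covariate the leaf count was 1124 and the R1 count 502, and with reference transcripts alone 1125 and 1338, with 215, 204 and 322 at V12, V14 and V16. The compared stage alone in the fit gave 363 at V12, 499 at V16 and 3023 at R1. Leaving out well-watered library 3 at V16 gave 681 at that stage. At R1 drought leaf libraries also differed in mean transcript length (1748 against 1671 nt), in the share of the transcript with the longer 5′ end (29.47% against 19.48%) and in transcripts at 0 (26.78% against 38.61%). Each had an exact p of 0.0286, with adjusted p of 0.171, 0.171 and 0.114. The share of the longer 5′ end rests on 148 pairs of transcripts.

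In ear under drought, the MADS-box gene m15 (GRMZM2G553379) had its main transcript at 81.8% ± 3.08 against 43.4% ± 11.9 in well-watered plants (SD, n = 16; adjusted p = 2.88e-11, limma). The glutathione transferase gst14 (GRMZM2G175134) was at 37.6% ± 5.63 against 0.2% ± 0.8, and an argonaute1 transcript (GRMZM2G162525), of the small RNA pathway, at 10.3% ± 27.2 against 95% ± 15.1. Auxin response genes were called in 4 of 16 cases (5 adjusted over the list alone), meristem regulators in 3 of 17 (3), splicing factors in 2 of 6 (3) and pollen and anther genes in 2 of 5 (3). MADS-box genes were called in 2 of 17 cases (2), oxidative stress enzymes in 2 of 15 (2), and heat shock genes in 0 of 10 (0, with 2 at an unadjusted p below 0.05 in limma). Of the 28 ear genes followed by name 18 kept their call in every alternative fit. Over the 4 stages the ear count of 1847 became 831 with reference transcripts alone and 997 with a change of at least 20 points. Of 100 splits of the labels 2, the real one included, were as large (highest other 1971). Stage counts were 879, 734, 546 and 6449 at V12, V14, V16 and R1, and with reference transcripts alone 376, 297, 282 and 1978. At V16, 4 of 35 splits of the labels, the real one included, called 546 genes or more (highest 3809), and the compared stage alone in the fit gave 252. At R1 the mean transcript length was 1616 ± 39.3 nt in drought and 1720 ± 21.7 nt in well-watered ear (n = 4 each; exact p = 0.0286, adjusted p = 0.171). The transcripts gained in drought at R1 coded a shorter protein in 4520 of 6413 genes and a longer one in 1095. The R1 count was 520 with mean transcript length as a covariate and 778 without 6 libraries of short mean transcript length. Leaving out drought library 4 gave 2874 and leaving out well-watered library 1 gave 3980.

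**Figure D5:**
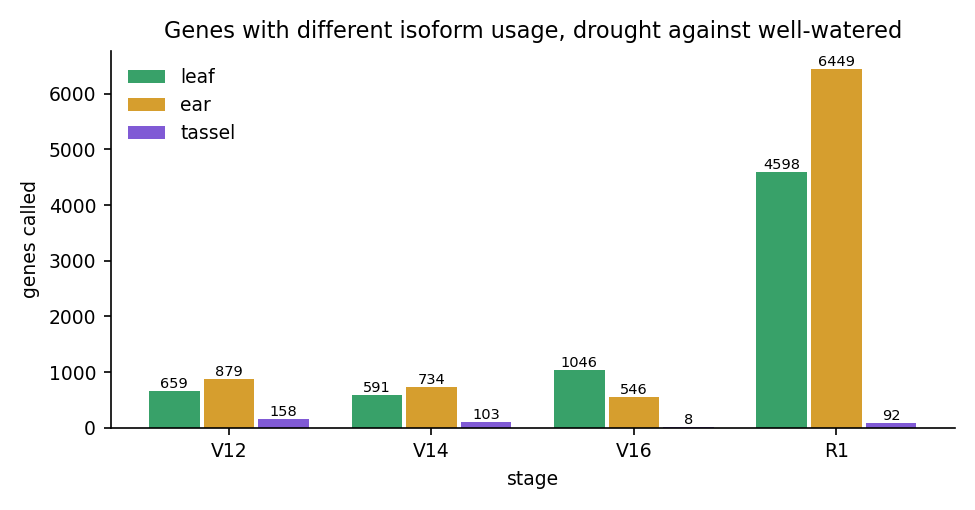
Number of genes called under drought (vertical axis) by organ and stage, in limma over groups of 4 libraries (3 for drought tassel at V12 and well-watered tassel at R1). The highest count in ear was 6449 and in leaf 4598, both at R1, and in tassel 158 at V12.

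Whether drought acted differently between stages or organs was tested as an interaction (limma F test). The genes named are those with the smallest adjusted p among tested genes with a symbol. The MADS-box gene m5 (GRMZM2G171365) changed under drought in leaf by -9.14, -1.57, -8.97 and -69.2 points at V12, V14, V16 and R1 (adjusted p = 7.97e-08). In the same order the values were 0, 0, 51.2 and 62.4 for mbd106 (adjusted p = 0.00142) and -6.89, -3.03, -13.2 and -49.2 for Cullin-4 (GRMZM2G704093; adjusted p = 0.00276), a ubiquitin ligase scaffold gene. In ear the smallest adjusted p belonged to INO1 (GRMZM2G155242; 30.3, 7.12, 3.18 and 3.46 points; 0.00964), bHLH173 (GRMZM5G882527; -3.74, 58.2, 44.5 and -32.1; 0.0215) and ZAR3 (GRMZM2G137546; -54.2, -33.6, -28.8 and -18.9; 0.0245). In tassel they were cyclin4 (-3.17, -27, 2.59 and 1.57; 0.00198), serk2 (GRMZM2G115420; 0.825, 25.2, -3.35 and -5.95; 0.0024) and serk1 (-3.15, 8.53, -28.6 and 99.3; 0.0065). Genes with a stage interaction numbered 132 in leaf, 184 in ear and 49 in tassel, and 18, 17 and 6 of these had a name. With mean transcript length as a covariate the counts were 5 in leaf and 52 in ear, with reference transcripts alone 40, 103 and 19, and with the replicate block 89 in ear. Leaving out single libraries gave 68 to 202 in leaf, 41 to 2790 in ear (the highest without drought library 1 at R1) and 41 to 76 in tassel. Between organs the drought change differed in 3961 of 12851 genes (388 named). The smallest adjusted p belonged to br2 (-90.3 points in leaf, -82.9 in ear and 0.186 in tassel; 3.14e-60), rps6 (33.9, 28.9 and 0.00283; 1.7e-47) and LIM6 (-71.2, -81.8 and 0.223; 2.53e-44), all 3 with the set difference of leaf and ear libraries described above. The count between organs was 1605 with mean transcript length as a covariate and 1154 with reference transcripts alone.

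The effective number of isoforms per gene, the exponential of the Shannon entropy of usage averaged over genes, summarised how evenly transcripts share a gene. It was 2.094 ± 0.0861 in drought and 1.97 ± 0.102 in well-watered leaf (SD, n = 16 each), a difference of 0.124 (two-sided permutation test within stages, p = 0.00148, adjusted p = 0.00444). That test took the 16 libraries of each treatment as independent. By stage the leaf means in drought and well-watered libraries were 2.033 and 1.954 at V12, 2.106 and 2.012 at V14, 2.059 and 2.041 at V16, and 2.179 and 1.874 at R1 (n = 4 each), so R1 gave most of the difference. The larger number of genes with a value in drought leaf libraries stood beside it at all 4 stages, and at R1 so did longer transcripts, a larger share of longer 5′ ends and fewer transcripts at 0. In ear the values were 2.03 ± 0.177 and 2.106 ± 0.154 (n = 16 each; difference -0.0759, adjusted p = 0.295), with 1.81 and 2.167 at R1. In tassel they were 2.139 ± 0.0546 and 2.142 ± 0.0506 (n = 15 each; stage-balanced difference 0.000533, adjusted p = 0.963).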

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

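The tests with the values -8.408, 96.9, 386, 1.008 and -3.082 were chosen after the results they concern were seen, as were the fits with mean transcript length as a covariate, and those with the values 25 and -4.32 and the criterion for 520 were written before.

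Single libraries far from the other 3 of their group were looked for in 198 sets of 4, where chance alone gives about 1 in 20, or 9.9 sets, and 16 were found. In the number of genes with a value these were well-watered leaf library 3 at V16 (30100, others 31000 to 31100) and drought tassel library 4 at V16 (37500, others 35800 to 36000). The effective number of isoforms set apart drought leaf libraries 1 at V14 (2.09, others 2.17 to 2.18), 1 at V16 (2.24, others 2.05 to 2.07) and 3 at R1 (2.16, others 2.26). Drought leaf library 1 at V14 also had 31.3% of its transcripts at 0 (others 27.1% to 27.6%). The usage of transcripts outside the reference annotation was far from the rest in well-watered ear library 1 at R1 (29.4%, others 31.4% to 31.8%) and in drought tassel libraries 1 at V14 (30%, others 29.1% to 29.2%) and 1 at V16 (29.8%, others 29.3% to 29.4%). The share of intron-retaining transcripts was so in well-watered leaf library 3 at R1 (42.4%, others 40.4% to 40.8%), drought leaf library 1 at V14 (41.5%, others 43.1% to 43.3%) and drought ear library 3 at V14 (46.3%, others 45.6% to 45.7%). For transcripts with an extra internal segment the libraries were well-watered leaf 4 at V12 (58.1%, others 51.7% to 52.1%), well-watered leaf 3 at R1 (53.8%, others 49.5% to 50.2%) and well-watered tassel 2 at V12 (61%, others 61.6%). The transcript with the longer 3′ end took 17.6% in drought ear library 1 at V14 (others 16.9% to 17%).

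Drought changes differed between groups in 4 interaction tests. They were 132 genes between stages in leaf, 184 in ear and 49 in tassel, and 3961 genes between organs. Residuals of a fit without the tested interaction were shuffled over all libraries of the fit, for 100 counts with the real one included. This gave at most 2 genes in leaf (1 as large), 2 in tassel (1 as large) and 1 between organs (1 as large). The shuffles moved residuals between stages, and for organs between organs, so they take the spread of all groups as alike. Under that assumption chance is excluded there. In ear 2 of 100 counts were as large, the real one included, and the highest other was 3210. That count is many times the real one and points to a structure of the ear libraries other than water and stage.

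In the 148 pairs where 1 transcript starts inside the other, transcripts with the longer 5′ end were used less in drought ear at R1. They took 16.32% ± 4.337 in drought and 24.73% ± 2.294 in well-watered libraries (SD, n = 4 each), a difference of -8.408 points (two-sided exact permutation test, p = 0.0571). The share with the longer 3′ end differed by 2.195 points the other way, which is what loss of 5′ ends of the RNA may leave, but the p does not pass 0.05, so that explanation stays open. By a criterion written before the test, drought was to be ruled out if under 10% of the 6449 calls at R1 were left with mean transcript length as a covariate, and 520 were left. That criterion was wrong, and it was changed after the result was seen: the covariate is made from the same usage values and separates the groups without overlap (1576 to 1668 nt in drought, 1688 to 1735 nt in well-watered), so drought and loss of 5′ ends cannot be told apart at this stage.

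More genes had a value in drought than in well-watered libraries of leaf and ear. Reads from genomic DNA were predicted to bring more single-exon genes. Only genes alone in their locus were counted. Single-exon genes were 25% (95% interval 23.5% to 26.6%) of 3050 genes listed in most drought and few well-watered leaf libraries. They were 43.7% (42.5% to 44.9%) of 6911 genes listed in some but not all tassel libraries, which are of a separate library series. The predicted excess was absent. Genomic reads can also fall on genes with several exons, so genomic DNA stays open. Unlike first written, the value says nothing of unspliced RNA. A difference between sets of libraries, or in how they were quantified, is a candidate explanation for the transcripts at exactly 0 in all libraries of a treatment: of 64 such transcripts in leaf with a value in all ear libraries, 96.9% averaged under 1% in well-watered and 5% or more in drought ear (25 met the exact rule there), and 66 of 68 averaged below 1% in drought tassel. Drought stays open, since the mean gap of 386 genes in tassel would also follow from a response of leaf and ear alone. These values cover the all-or-none transcripts, not all 3644 genes called in leaf.

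Intron-retaining transcripts took a smaller share in tassel at R1 than at V12. The transcript with the longer 5′ end took 1.008 points more at R1 (30.99% ± 0.906 to 31.99% ± 1.00, two-sided exact permutation test, p = 0.257). In drought tassel it differed by -0.2354 points. Neither change goes beyond its spread, and the share rests on 148 pairs. Mean transcript length differed by -12.15 nt in well-watered tassel, so loss of 5′ ends is not excluded. The fall did not rest on pairs that hold a transcript outside the reference annotation: 1254 pairs of reference transcripts went from 35.04% ± 0.636 to 30.71% ± 0.188, a difference of -4.32 (exact p = 0.0286). The deposited values are shares over all transcripts of a gene, those outside the annotation included. An effect of the latter on how reads were assigned is therefore not excluded. The fall was not limited to well-watered plants, with -3.082 points in drought, and other extra internal segments fell too (-1.68 points, exact p = 0.0286, adjusted p = 0.0571). The number of genes with a value rose as the share fell from V12 to V16 (32980, 35270 and 35770 genes, against 46.62%, 45.98% and 44.26%). At R1 it was 35400, against 43.16%. In drought tassel the values by stage were 33320, 35220, 36300 and 36120 genes, against 46.93%, 46.16%, 44.24% and 43.85%. A link with the number of genes with a value stays open. So do depth, which is unknown, and the stage of the tassel, with no test of splicing or of cell types.

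Other splits of the same libraries were counted for each result that compares groups (35 splits for 4 against 4 or 4 against 3, otherwise 100). Chance is excluded for drought in leaf (3644 genes, highest other split 305) and in leaf at V12 (659, highest 21), V14 (591, highest 4), V16 (1046, highest 14) and R1 (4598, highest 31), where 1 split, the real one, was as large. For development the same holds in ear (224, highest 4) and tassel (2329, highest 934), but in leaf 3 of 35 splits were as large as the real 73 (highest 92), so chance is not excluded. Drought in ear (1847) was reached by 2 of 100 splits, the real one included. The highest other split called 1971 genes, more than the real one, so chance and a library structure apart from water are not excluded there. In ear at V12 (879, highest 36), V14 (734, highest 33) and R1 (6449, highest 2371) only the real split was as large, which excludes chance. At V16 in ear 4 of 35 splits were as large as the real 546, and the highest called 3809, so chance is not excluded and the libraries have a structure apart from water. In tassel chance is excluded for drought over all stages (103, highest 8), with 1 split as large. At V12 (158, highest 127), V14 (103, highest 11) and R1 (92, highest 60) only the real split was as large. At V12 and R1 the other splits called a median of 49 and 24.5 genes, so part of these counts can arise by chance. With the compared stage alone in the fit 1, 13 and 5 genes were called at V12, V14 and R1. Chance is therefore not excluded at these stages, nor at V16 (8 genes, 3 of 35 splits, highest 11). Chance is excluded between ear and leaf (4981, highest 4504), tassel and leaf (8413, highest 5028) and tassel and ear (6256, highest 3318), again with 1 split of 100 as large.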

How the results depend on the processing

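Settings added after the data were seen were the covariate, the fits without 6 libraries of short mean transcript length, the fits on the compared groups alone and the drought libraries. All other settings were named before the data were examined. Of those named, a pseudocount of 0.1 FPKM, a pseudo-FPKM of 0.1, a minimum of 5 FPKM, the fits without a filter, the rescaling of libraries, all other settings for gene level and the estimated correlation of gene lists were not run, because the values are percentages. Unless a cause is named, the cause was not tested.

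With a change of at least 20 points, which can only lower a count, 1503 genes were called for drought in leaf, 997 in ear and 22 in tassel, 2099 between ear and leaf and 3029 between tassel and ear. The other usage counts stayed within 1.5 times.

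Taking the replicate number as a block moved the ear stage interaction to 89 genes and drought in tassel at V16 to 5. The block turned the tassel difference in the effective number of isoforms to -0.00475 (adjusted p = 0.685). Block counts were otherwise within 1.5 times. The numbers do not mark a shared block in the values: of 46 same-numbered pairs of drought and well-watered libraries 4 correlated above 0.1 in their deviations from the group means, and 16 libraries correlated best with their own number.

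With reference transcripts alone fewer transcripts are tested. Drought counts were then 1125 in leaf, with 215, 204, 322 and 1338 at V12, V14, V16 and R1; 831 in ear, with 376, 297, 282 and 1978; and 26 in tassel, with 65, 31 and 33 at V12, V14 and R1. Development gave 40 in leaf, 102 in ear and 961 in tassel, and the stage interactions 40, 103 and 19. Organs differed in 1837 genes (ear and leaf), 2901 (tassel and leaf) and 2005 (tassel and ear), and the interaction of organs was 1154.

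By diffSplice the counts were 1002 for drought in leaf at V12, 479 and 453 for development in leaf and ear, and 290 for drought in tassel, with 612, 272, 89 and 372 at its 4 stages. Other diffSplice counts stayed within 1.5 times.

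With mean transcript length as a covariate drought called 1124 genes in leaf, 586 at V16 and 502 at R1, and 520 in ear at R1. The stage interactions became 5 in leaf and 52 in ear, tassel development 920, tassel and leaf 4155, tassel and ear 3072 and the interaction of organs 1605. The covariate is made from the same usage values, so it also takes away real change that follows transcript length. Without the 6 libraries of short mean length 778 genes were called for drought in ear at R1, where 1 drought library is left and is assumed to vary like the other groups.

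Fits on the compared groups alone, with fewer degrees of freedom, called 363, 499 and 3023 genes for drought in leaf at V12, V16 and R1, 252 in ear at V16, and 1, 13, 1 and 5 in tassel at its 4 stages. Development gave 7 in leaf, 594 in ear and 965 in tassel.

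In the drought libraries development called 843 genes in leaf and 8348 in ear, and genes with a value more often in leaf and in ear than in tassel numbered 7768 and 6596.

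Named genes were counted once per comparison, so a gene can recur. With the covariate 148 of these pairs of gene and comparison were the same, 118 lost their call and 26 reversed. The reversed changes in points were Hsp70 -0.249, cat1 -2.36, ARF13 0.485 and GI 1.84 for drought in leaf. Between tassel and leaf they were PDK1 28.3, Hsp70 -2.88, SnRK2.1 3.14, SnRK2.6 -21.3, SH-1 -12.2, PIP1-3 -1.15, cat1 15, cycD2 13.8, PCNA 11.9, DBB11 6.69, CesA-2 12.1, TPS2 10.8, TPS9 9.03 and EREB94 11.8. Between tassel and ear they were PDK1 -4.47, Hsf05 4.92, Hsp70 -9.63, ABI22 -1.29, rps4 4.99, ARF17 -4.94, ARF18 7.52 and ARF1 8.86.

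In the drought libraries 131 pairs of named gene and comparison were the same, 59 lost their call and 28 reversed. Those reversed were Nramp1 1.12 in leaf development, GRF14 -0.0247 in ear, and serk1 3.13, ZAG5 -4.32, plt2 -0.145 and ZCN14 6.32 in tassel. Between ear and leaf they were ABI22 -6.4, Lsi6 -10.7, cat1 -4.62, cycD2 1.93, srp30 19.8, CesA-2 18.6, CesA-5 -2.19, TPS4 1.49, TPS2 12.1, ARF17 -3.49, ARF18 4.67, ARF3 -2.05, EREB94 4.47 and gigz1b 7.99. Tassel and leaf had PDK1 7.36, SH-1 -1.14, Lsi6 -4.94, PIP1-3 -15, L29 4.24, EREB94 1.42 and bronze-2 -2.65, and tassel and ear had expB8 -1.86. In the remaining settings 0 such pairs reversed. Calls were lost by 9 pairs with the block (283 the same), 29 with reference transcripts (126 the same), 21 without the 6 libraries (191 the same) and 21 on the compared groups (22 the same).

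Leaving out single libraries kept the overall drought counts of leaf and ear, the 3 organ contrasts and the interaction of organs within 1.5 times. Drought in leaf at V16 ran from 681 (without well-watered 3) to 1282, and leaf development from 45 to 178 (without well-watered V12 libraries 1, 2 and 3: 47, 45 and 124; without R1 libraries 2 and 3: 118 and 178). The leaf stage interaction ran from 68 to 202 (without well-watered V12 library 3 202, R1 library 2 79, drought R1 libraries 1 and 4 68 and 86). Drought in ear at R1 ran from 2874 (without drought 4) to 7685, with 3980 without well-watered 1. Ear development ran from 115 to 176, all below the full 224; without V12 library 1 it was 134, and without R1 libraries 1 to 4 133, 120, 115 and 127.

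The ear stage interaction ran from 41 to 2790. Without well-watered libraries 1 to 4 it was 80, 86, 117 and 79 for V12 and 66, 687, 75 and 85 for V14, without V16 libraries 1 and 4 1829 and 1494, and without R1 libraries 1 to 3 42, 41 and 43. Without drought libraries it was 306 (V12, 4), 118, 100 and 100 (V14, 2 to 4), 109, 604 and 119 (V16, 1 to 3), and 2790, 75 and 66 (R1, 1, 3 and 4).

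Drought in tassel ran from 68 (without V12 drought 3) to 131. At V14 it ran from 51 to 104 (without well-watered 1, 2 and 3: 67, 58 and 65; without drought 1, 2 and 4: 53, 51 and 65), at V16 from 2 to 17 (without well-watered 2 and 3: 2 and 4; without drought 2, 3 and 4: 14, 17 and 13) and at R1 from 70 to 192 (without well-watered 1). The tassel stage interaction ran from 41 to 76 (without V12 drought 2), and the effective number of isoforms in tassel from -0.00406 to 0.0061, on both sides of 0. Genes with a value more often in tassel than in ear ran from 2615 to 4743 and the reverse from 654 to 1227, and the lower values came without an ear library: 2615 to 2809 for each of 14 well-watered ones (all but libraries 1 and 4 at R1) and 654 to 694 for each of the 16. Of the named genes 7678 such refits were the same, 469 lost their call and 0 reversed.

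Depth is unknown for all libraries, so how far it limits these counts was not tested.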

Other observations

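The counts of genes with a value in more libraries of an organ than of another, and their lists, were computed after the unit of the table was known, and the tests on them are among those chosen later.

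Whether a gene had any value in a library differed between the organs, and no test set the lists below against all genes. The knotted-like homeobox genes gnarley1 and knox8, the meristem size regulator FEA4 and HB39 had a value in 16 of 16 well-watered ear libraries and 0 of 16 leaf libraries (two-sided Fisher's exact test, adjusted p = 9.76e-08 each). Of 24 meristem regulators with a value in either organ 13 had one more often in ear, as did 18 of 40 MADS-box genes, with 1 the other way. The anther genes ms23 (15 of 15 tassel and 0 of 16 leaf libraries, adjusted p = 2.58e-07) and ms8 (11 and 0, adjusted p = 0.000278) were among 14 of 21 pollen and anther genes listed more often in tassel than in leaf, and 10 of 21 were so against ear. Cell cycle genes were listed more often in ear and in tassel than in leaf in 8 of 13 cases each, among them cyc3 and cyclin11 (16 ear and 0 leaf libraries) and the replication licensing genes MCM6 and MCM7 (16 and 1). The inflorescence branching genes bd1 and BA1 had a value in 15 of 16 ear and 0 of 15 tassel libraries (adjusted p = 1.72e-05 each), and ra1 in 10 and 0 (adjusted p = 0.00579). Of 39 oxidative stress enzymes 12 were listed more often in leaf and 4 in ear, and 23 had no call. Of 7 light harvesting proteins 1 was listed more often in leaf, and 6 had no call.

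In all, 4267 genes were listed more often in ear than in leaf and 4134 less often, out of 49166 with a value in either. Tassel exceeded leaf in 7066 genes and fell short in 2505, and it exceeded ear in 4261 and fell short in 1048. The last pair of counts moved with single libraries: without an ear library they fell to 2615 and 654 at the lowest, the latter to 694 or less for each of the 16. Chance is excluded for each of these 6 counts, with 1 of 100 splits as large and 0 genes in the highest other split. What a missing value stands for is not stated, so a gene without a value is not shown to be silent. The comparisons with tassel change in the drought libraries, where 7768 genes were listed more often in leaf and 6596 in ear.

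The 6 libraries of short mean transcript length all came from ear at V16 or R1. They include every drought ear library at R1 but library 1, which was at 1668 nt. The 6 were found by the widest gap between the sorted values of leaf and ear (1621 and 1651 nt), a rule chosen after the values were seen. Their values are 1602 and 1580 nt for well-watered libraries 2 and 3 at V16, 1621 nt for drought library 2 at V16, and 1621, 1599 and 1576 nt for drought libraries 2, 3 and 4 at R1. Drought library 4 at R1 also had the lowest effective number of isoforms of the 6, 1.518, and 50.59% of its transcripts at 0.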
